A study of Homo sapiens with 60 samples.

How the data were processed

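Total RNA from A549 cells, an established human lung adenocarcinoma line, was sequenced after 24 h with an ethanol extract of a medicinal plant or plant formula, or with vehicle. The 60 libraries used here covered 8 extracts at 3 doses (500, 100 and 20 ug/mL, called high, medium and low) and 3 vehicle libraries. The labels give vehicle as 0.1% DMSO, whereas the description of the series names 2% DMSO, and which figure applies was not settled here. The DMSO share of the extract libraries is not given in the sources used here. The series description also lowers the doses of an extract that was toxic below the highest dose, to steps set by its own toxicity, whereas the labels give the same 3 doses for every extract, so the doses named here may be nominal. Per the labels' protocols the libraries came from a directional kit and were sequenced with reads of 100 bases. Per the submitters' processing notes the reads passed through FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with a human GRCh38 (hg38) genome. The annotation release and the strand setting of the counting are not given in the sources used here. Antisense genes, overlapping genes and near-identical copies are therefore given as uncertain, though some such genes may be printed without that mark.

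The authors deposited a table of RSEM expected counts for 60675 genes, in which reads that match several genes are divided among them, so values need not be whole. Of the values used, 8.6% were not whole within a tolerance of 1e-09, and all were rounded to whole counts before testing. The table has 270 columns of samples, and 210 of them, which belong to samples not analysed here, were not used. Columns were matched to samples by name, and every sample's group came from its labels. Gene identifiers were paired with symbols and positions of GENCODE v29 on GRCh38, which gave 57055 identifiers a symbol.

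Vehicle had 3 libraries. Angelicae Gigantis Radix, Paeoniae Radix and Sagunja-tang had 2 libraries per dose, Cnidii Rhizoma, Rehmanniae Radix Preparata, Astragali Radix and Cinnamomi Cortex had 3, and Samul-tang had 1. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical. Library totals ran from 17921160 to 27653936 expected counts. The titles of all 60 libraries name the same batch (BatchD), while the sample codes in the labels fall into series. Vehicle has a code series of its own (D1), and the extracts share others in pairs, so a comparison with vehicle cannot separate an extract from its code series, whereas a comparison of doses stays within 1 series.

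The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) on the rounded counts, with TMM scaling, filterByExpr on the 25 groups and 1 mean per group in a single fit of all 60 libraries. The filter kept 17717 genes and removed 42958. The fit had 35 residual degrees of freedom, a prior of 9.54 degrees of freedom and a common biological coefficient of variation of 0.0485. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene printed here is from this edgeR test unless another is named. The standard error given with a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic, and levels are CPM, counts scaled to the TMM-scaled library size, with the SD between libraries. For genes at 0 in every library of a group, folds are bounds against a floor of 3 counts per library, which was 0.1355 CPM in vehicle. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

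The comparisons, the test, the list of alternatives, 29 gene lists, a panel of 10 genes and the rule for naming genes were chosen before the data were examined. Lists with at least 5 tested members were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. Members called are counted over all genes tested and also adjusted over the list alone. By the naming rule, each extract at the high dose against vehicle contributed the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, a mean of at least 2 CPM and every treated library on one side of every vehicle library. It also contributed up to 4 called members of each list that was called or had at least 3 called members, and the panel. The high dose against the low dose, and extract against extract, contributed 3 genes in each direction by the first part of the rule, and the panel. Samul-tang contributed 5 genes in each direction by difference of log2(CPM + 1) at the high dose, with a mean of at least 5 CPM and the same sign at the medium dose, and the panel. Naming list members was extended to high against low dose and to extract against extract after the data were seen. The text prints a part of the genes so chosen.

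Samul-tang, with 1 library per dose, had no test. Its log2(CPM + 1) differences from the vehicle mean are given, and a list's median is placed among 10000 random lists of the same size matched on mean expression in 20 bins. Similarity of dose responses was the Pearson correlation, across the 17717 genes, of the difference between high and low dose in mean log2(CPM + 1) for each of the 28 pairs of extracts. Genes are not independent replicates, so no p is attached.

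The alternatives were DESeq2 1.42.0, median-of-ratios (RLE) scaling, no filter on low counts, the replicate number as a block, a fit of only the groups compared, leaving out each library in turn, other pseudocounts of 0.5 and 5 CPM, genes with a mean of at least 10 CPM, and medium in place of high dose for the similarity. Removing each library's trend with GC content and gene length, by offsets from splines, was added after the data were seen, as was the contrast of all low-dose libraries with vehicle. The GC trend was fitted on 10731 protein-coding genes. RLE in place of TMM shifted comparisons by -0.006 to 0.012 on the log2 scale. The replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. Among comparisons with 3 such pairs, every correlation was above 0.1 in 3, namely Astragali Radix high against vehicle (0.118 to 0.26), Cinnamomi Cortex medium against vehicle (0.214 to 0.362) and Rehmanniae Radix Preparata high against low (0.103 to 0.301).

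The procedure was tested on simulated counts for 17717 genes with the real means and library sizes, with 100 genes changed at each fold. For Angelicae Gigantis Radix high against low, with 2 libraries a group, 50% of genes changed by 1.3-fold and 90% of those changed by 2-fold were recovered, with 9 false calls. For Cnidii Rhizoma high against low, with 3 libraries a group, the shares were 69% and 92%, with 4 false calls. Against vehicle the shares were 60% and 92% for Angelicae Gigantis Radix, with 11 false calls, and 73% and 92% for Cnidii Rhizoma, with 6 false calls. A planted GC trend, linear in the same GC values that the correction uses, gave 5671 calls, all of which the GC correction removed. Other tools used were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Libraries of other extracts and treatments of the series were not analysed here.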

Results

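The data were 60 RNA-seq libraries of A549 cells, a human lung adenocarcinoma line, each treated for 24 h. The extracts were ethanol extracts of Angelicae Gigantis Radix (angelica root), Paeoniae Radix (peony root), Cnidii Rhizoma, Rehmanniae Radix Preparata (processed rehmannia root), Astragali Radix (astragalus root) and Cinnamomi Cortex (cinnamon bark), and of 2 traditional formulas, Sagunja-tang and Samul-tang. The labels give 500, 100 and 20 ug/mL for each (high, medium and low dose), and 3 libraries came from vehicle. Angelicae Gigantis Radix, Paeoniae Radix and Sagunja-tang had 2 libraries per dose, Samul-tang had 1, and the other 4 extracts had 3. Libraries held 17921160 to 27653936 expected counts, and 17717 genes passed the filter on low counts. Log2 fold changes are given ± SE and levels in CPM (counts scaled to library size) ± SD. List tests were camera with Benjamini-Hochberg adjustment, and a list's call held with an estimated correlation unless a further p is given.

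Library-wide measures set 2 kinds of library apart. The share of counts on mitochondrial genes was 22.2 to 25.7% in the 3 libraries of Astragali Radix at the high dose and 22.0 to 23.9% at the medium dose. It was 15.0 to 18.5% in vehicle and 11.4 to 18.1% in all other libraries. Genes of the GC-richest decile exceeded those of the GC-poorest decile by 0.549 to 0.69 (log2, after centring each gene over libraries) in vehicle, by 0.751 to 1.118 in Astragali Radix at the high dose and by 0.3 to 0.581 at its medium dose. In the other 51 libraries this measure lay between -0.305 and 0.048. Between replicates, a chi-square per degree of freedom of 36.4 and 36.2 set Rehmanniae Radix Preparata medium replicate 1 apart from its fellows, which gave 2.42 with each other. Astragali Radix high replicate 3, the library of fewest counts (17921160), stood at 23.8 and 20.6 against 3.34.

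**Figure D1:**
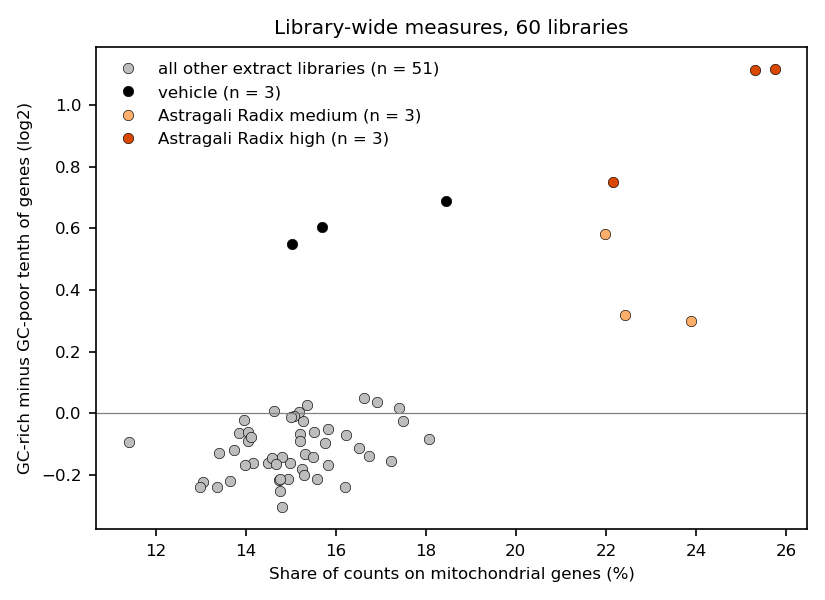
Each point is 1 of the 60 libraries, with the share of counts on mitochondrial genes (%) on the horizontal axis and the log2 difference between the GC-richest and GC-poorest deciles of genes on the vertical axis. Vehicle libraries lie at 0.549 to 0.69 and Astragali Radix high-dose libraries at 0.751 to 1.118 on the vertical axis, while the other 51 libraries apart from Astragali Radix medium dose lie between -0.305 and 0.048.

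Paeoniae Radix at the high against the low dose raised genes of the hypoxia response, of the ATF4 stress response and of the p53 pathway, and lowered mitotic and heat shock genes. IGFBP3, which binds insulin-like growth factors (ENSG00000146674, chromosome 7, 45912245 to 45921874), rose from 5.64 ± 0.130 to 76.5 ± 1.14 CPM (SD, n = 2 per dose; log2 fold change 3.76 ± 0.10, edgeR adjusted p = 3.4e-31), and vehicle stood at 4.63 ± 0.217 CPM. Of 23 hypoxia genes 22 rose and 1 was not called (23 rose adjusted over the list alone), with a median log2 fold change of 1.53 and a camera adjusted p of 2.4e-86. NDRG1, a gene induced by low oxygen, rose by 2.55 ± 0.06 to 583 ± 12.9 CPM, the glycolytic enzyme gene ALDOC by 2.33 ± 0.08 and PFKFB4 by 2.30 ± 0.12. HK2, whose product starts glycolysis (ENSG00000159399, chromosome 2, 74833981 to 74893359), rose by 2.88 ± 0.14. Of 21 ATF4 targets 16 rose and 5 were not called (16 adjusted over the list alone), with a median of 0.81 and a camera adjusted p of 9e-22. The stress transcription factor genes ATF3 and DDIT3 rose by 3.16 ± 0.20 and 1.77 ± 0.12, and CHAC1, which degrades glutathione, by 2.01 ± 0.20. Of 22 p53 targets 21 rose (21 adjusted over the list alone; median 0.76, camera adjusted p = 8.5e-16), among them GDF15 by 2.15 ± 0.12, the cell death gene BBC3 by 1.59 ± 0.13 and the cell cycle inhibitor CDKN1A by 1.19 ± 0.06.

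Other groups also moved with the dose of Paeoniae Radix. Of 19 immediate early and ERK feedback genes 18 rose (18 adjusted over the list alone; median 1.04, camera adjusted p = 1.4e-15), with EGR1 at 2.40 ± 0.24, FOS at 2.08 ± 0.10 and DUSP5 at 2.13 ± 0.09. Of 24 mitotic genes 17 fell, 1 rose and 6 were not called, with the same counts adjusted over the list alone (median -0.26, camera adjusted p = 1.8e-06). Of these, DLGAP5 fell by 1.98 ± 0.09, CENPE by 1.65 ± 0.16 and the proliferation marker MKI67 by 0.66 ± 0.12. Of 15 heat shock genes 11 fell and 4 were not called (12 adjusted over the list alone; median -0.48, camera adjusted p = 1.8e-06), among them HSPA4L by 2.04 ± 0.09 and HSPA1A by 0.98 ± 0.09, the latter uncertain because HSPA1B is nearly identical. Of 24 cholesterol synthesis genes 21 rose and 2 fell, also adjusted over the list alone (median 0.45, camera adjusted p = 1.3e-08). INSIG1 rose by 1.53 ± 0.06, while the synthesis enzyme gene HMGCS1 fell by 0.45 ± 0.06. Targets of the aryl hydrocarbon receptor (AHR) rose in 7 of 10 cases and fell in 2 (8 and 2 adjusted over the list alone; median 0.64, camera adjusted p = 3.4e-06), with TIPARP at 1.71 ± 0.06, CYP1B1 at 1.04 ± 0.05 and CYP1A1 at 2.71 ± 0.43 from a level of 0.271 ± 0.0301 CPM. LEFTY1, an inhibitor of Nodal signalling (ENSG00000243709, chromosome 1, 225886282 to 225911382), fell by 3.34 ± 0.13. Of 24 DNA replication genes 16 fell and 2 rose (16 and 3 adjusted over the list alone; camera adjusted p = 0.002, adjusted p = 0.13 with an estimated correlation). HMOX1 did not pass the test (0.02 ± 0.08, edgeR adjusted p = 0.88). In all, 9255 genes were called, 4698 higher and 4557 lower, of which 1965 differed at least 2-fold.

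Astragali Radix at the high against the low dose lowered every tested mitotic gene and raised hypoxia, cholesterol synthesis and lysosome genes. All 24 mitotic genes fell, also adjusted over the list alone, with a median of -1.56 and a camera adjusted p of 3.6e-33. CENPE, a kinetochore motor gene (ENSG00000138778, chromosome 4, 103105806 to 103198409), went from 24.8 ± 7.41 to 1.40 ± 0.553 CPM (SD, n = 3 per dose; log2 fold change -4.16 ± 0.23, edgeR adjusted p = 9.1e-21), with 29.8 ± 2.27 CPM in vehicle. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) fell by 2.7 ± 0.11 from 269 ± 22.7 to 41.4 ± 9.56 CPM, CENPF by 3.30 ± 0.12 and DLGAP5 by 2.49 ± 0.09. Of 24 DNA replication genes 21 fell and 1 rose, also adjusted over the list alone (median -0.82, camera adjusted p = 8e-11), with MCM10 at -1.88 ± 0.08 and CDC6 at -1.16 ± 0.05. Of 23 hypoxia genes 22 rose (22 adjusted over the list alone; median 1.05, camera adjusted p = 5.3e-28). ALDOC (ENSG00000109107, chromosome 17, 28573115 to 28577264) rose by 2.83 ± 0.06 from 17.5 ± 0.3 to 124 ± 11.7 CPM, ENO2 by 2.10 ± 0.07 and NDRG1 by 2.06 ± 0.04. Of 24 cholesterol synthesis genes 23 rose (23 adjusted over the list alone; median 0.76, camera adjusted p = 2.4e-19), among them the enzyme genes MVD by 1.93 ± 0.07, DHCR7 by 1.59 ± 0.05 and LSS by 1.41 ± 0.05. HMGCS1 was the member not called (0.02 ± 0.05). SCD, a fatty acid desaturase gene, rose by 1.29 ± 0.04. In these libraries the mitochondrial share was 22.2 to 25.7% and GC-rich genes stood higher, as given above, and log2 fold changes correlated with GC content across 10728 genes (Spearman rho = 0.635).

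Lysosome and autophagy genes rose in 18 of 20 cases with Astragali Radix and 1 fell, also adjusted over the list alone (median 0.84, camera adjusted p = 6.1e-16). NEU1, a lysosomal sialidase gene, rose by 1.87 ± 0.06 and the autophagy receptor gene SQSTM1 by 1.77 ± 0.07. CTSD, a lysosomal protease gene, rose by 1.63 ± 0.05, and by 0.95 with the GC and length trend removed. NRF2 targets of the oxidative stress response rose in 19 of 24 cases and fell in 5, also adjusted over the list alone (median 0.45, camera adjusted p = 3.5e-06, adjusted p = 0.041 with an estimated correlation). HMOX1, the gene of haem oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose by 1.70 ± 0.06 from 47.9 ± 2.41 to 156 ± 18.1 CPM (edgeR adjusted p = 7.6e-28), with 57.1 ± 2.83 CPM in vehicle, and NQO1 by 0.38 ± 0.04. The ferritin gene FTH1 rose by 1.22 ± 0.06 and FTL by 1.28 ± 0.08, or 0.64 with the GC and length trend removed, both with many pseudogenes and so uncertain. All 13 mitochondrially encoded genes rose, also adjusted over the list alone (median 0.80, camera adjusted p = 0.014, adjusted p = 0.51 with an estimated correlation), with MT-CO1 at 1.21 ± 0.12. Of 10 AHR targets 8 rose and 2 fell, also adjusted over the list alone (median 0.74, camera adjusted p = 0.0019), and CYP1A1 rose by 2.57 ± 0.37 to 1.73 ± 0.221 CPM. Of 15 heat shock genes 8 fell and 2 rose, also adjusted over the list alone (median -0.28, or -0.55 with the GC and length trend removed, camera adjusted p = 3.5e-06), with HSP90AA1 at -2.16 ± 0.06 and HSPH1 at -1.55 ± 0.06. HSPA1A did not pass the test (-0.06 ± 0.07). PAPPA-AS1, antisense to its neighbour and so uncertain, was at 0 in every high-dose library and at 14.94 CPM at the low dose, at least 75.5-fold lower. Its level also varied widely between vehicle libraries (6.225 ± 6.063 CPM). CD68, of the leukocyte markers, rose by 2.09 ± 0.14 from 14.2 ± 1.79 to 60.6 ± 6.86 CPM, while the leukocyte list was not called (4 of 6 members rose, camera adjusted p = 0.23). The test called 11136 genes, 5698 higher and 5438 lower, and 2611 at least 2-fold apart.

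**Figure D2:**
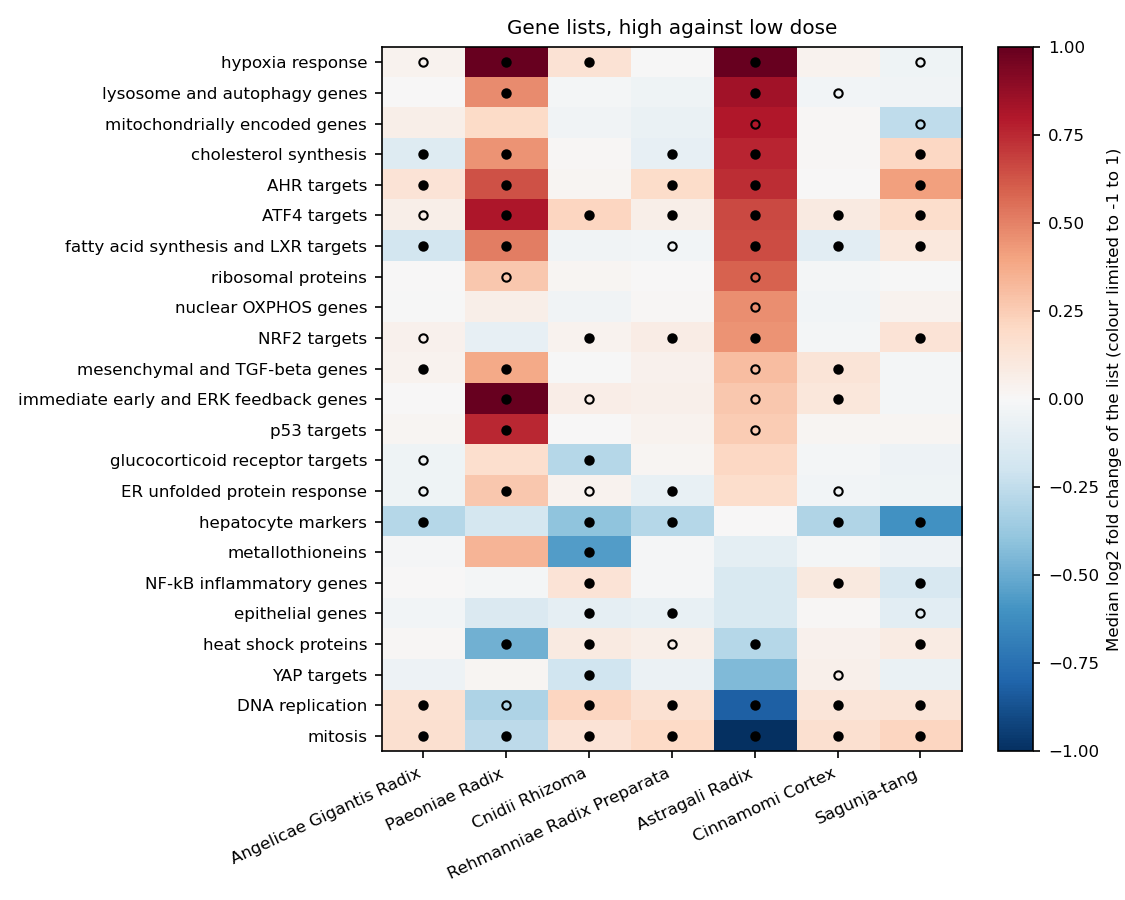
Colour gives the median log2 fold change of gene lists (vertical axis) at the high against the low dose of each replicated extract (horizontal axis), limited to -1 to 1. Lists of interferon response, replication-dependent histones, drug metabolism and transport, and leukocyte, neuronal and fibroblast markers are not shown. Of these, drug metabolism and transport stood at -0.835 in Paeoniae Radix, and the histones at 0.56 there and 0.86 in Astragali Radix. Dots mark lists called by camera, filled where the call held with an estimated correlation and open where it was lost; the hypoxia list stood at 1.53 in Paeoniae Radix and 1.05 in Astragali Radix, and the mitosis list at -0.26 and -1.56.

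Cnidii Rhizoma at the high against the low dose raised HMOX1 and DNA replication genes and lowered glucocorticoid receptor targets and metallothioneins. HMOX1 rose by 1.26 ± 0.06 from 44.6 ± 2.64 to 107 ± 1.97 CPM (SD, n = 3 per dose; edgeR adjusted p = 2.4e-21). Of 15 glucocorticoid receptor targets 10 fell, 1 rose and 4 were not called (13 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 1.2e-17). TSC22D3 (ENSG00000157514, chromosome X, 107713221 to 107777342) fell by 0.82 ± 0.04 from 209 ± 7.05 to 118 ± 4.78 CPM (edgeR adjusted p = 2.0e-21), with 225 ± 9.70 CPM in vehicle, and the transcription factor gene KLF9 fell by 0.67 ± 0.05. The member that rose was ANGPTL4, an inhibitor of lipoprotein lipase and also a hypoxia gene (ENSG00000167772, chromosome 19, 8363289 to 8374373), by 1.18 ± 0.05 to 99.8 ± 4.57 CPM. Of 5 metallothionein genes, which bind metals, 3 fell, also adjusted over the list alone (median -0.56, camera adjusted p = 8.8e-07), with MT1X at -1.03 ± 0.09 and MT2A at -0.56 ± 0.12, each uncertain as a member of a family of close copies. DNA replication genes rose in 15 of 24 cases (21 adjusted over the list alone; median 0.21, camera adjusted p = 2.7e-19), with POLE2 at 0.51 ± 0.08 and CDC6 at 0.40 ± 0.04, and mitotic genes in 9 of 24 (13 adjusted over the list alone; median 0.14, camera adjusted p = 1.9e-08). PLIN1, a coat protein gene of lipid droplets, rose by 1.3 ± 0.17 and the glutathione synthesis gene GCLM by 0.48 ± 0.05. HP, the haptoglobin gene, fell by 1.71 ± 0.19, STAC2 by 1.3 ± 0.16 and SLC10A1, a bile acid transporter gene, by 1.23 ± 0.18. Of 13 YAP targets 7 fell (8 fell and 1 rose adjusted over the list alone; median -0.20, camera adjusted p = 8.1e-07), among them ANKRD1 by 0.64 ± 0.06 and AMOTL2 by 0.44 ± 0.06. CYP1A1 did not pass the test (0.04 ± 0.47), and CYP1B1 rose by 0.35 ± 0.04. The test called 1477 genes, 675 higher and 802 lower.

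**Figure D3:**
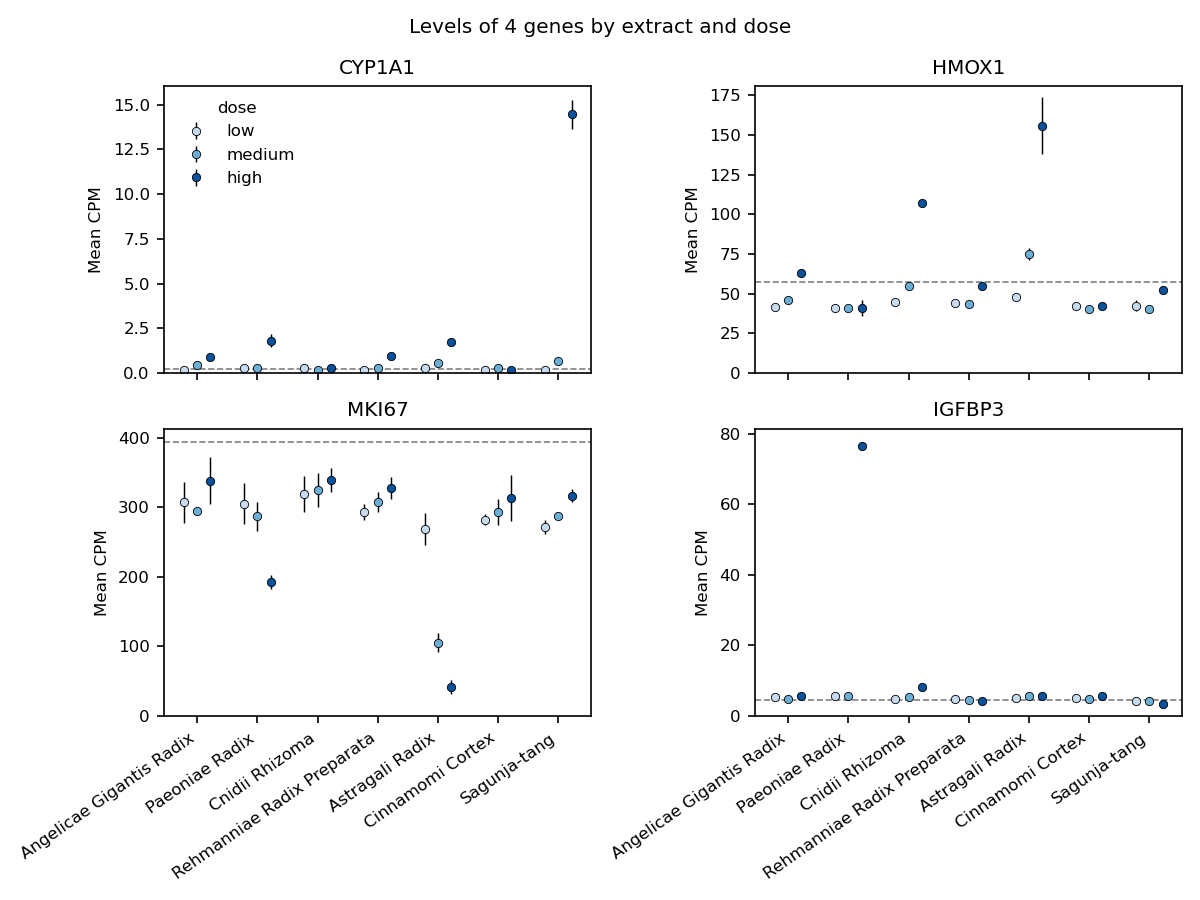
Mean level in CPM (vertical axes, starting at 0) of CYP1A1, HMOX1, MKI67 and IGFBP3 for each replicated extract (horizontal axis) at the low, medium and high dose, with bars of 1 SD and a dashed line at the vehicle mean. CYP1A1 reached 14.5 CPM with Sagunja-tang, HMOX1 156 CPM with Astragali Radix and IGFBP3 76.5 CPM with Paeoniae Radix, and MKI67 was at 41.4 CPM with Astragali Radix at the high dose.

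Sagunja-tang at the high against the low dose raised AHR targets and lowered hepatocyte marker genes. CYP1A1, a classic AHR target (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose from 0.162 ± 0.118 to 14.5 ± 0.812 CPM (SD, n = 2 per dose; log2 fold change 6.45 ± 0.38, edgeR adjusted p = 3.4e-17), with 0.214 ± 0.0824 CPM in vehicle. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) rose by 1.12 ± 0.05 from 131 ± 3.38 to 286 ± 4.90 CPM and ALDH3A1 by 0.93 ± 0.06. Of 10 AHR targets 7 rose and 3 were not called (9 adjusted over the list alone; median 0.41, camera adjusted p = 3.8e-65). Of 8 tested genes of the hepatocyte list 5 fell (6 fell and 1 rose adjusted over the list alone; median -0.60, camera adjusted p = 7.9e-24). APOB fell by 0.95 ± 0.13, SERPINA1 by 0.80 ± 0.10, TF by 0.62 ± 0.11 and the fibrinogen gene FGB by 0.60 ± 0.05 from 973 ± 4.87 CPM. CLDN2, a tight junction gene (ENSG00000165376, chromosome X, 106900164 to 106930861), fell by 1.51 ± 0.18, ACY3 by 1.39 ± 0.21 and the microvillus gene VIL1 by 1.3 ± 0.25. Cholesterol synthesis genes rose in 10 of 24 cases (17 adjusted over the list alone; median 0.20, camera adjusted p = 7.1e-18), with FDPS at 0.37 ± 0.05. Mitotic genes rose in 6 of 24 cases (19 adjusted over the list alone; median 0.22, camera adjusted p = 1.1e-16), and NRF2 targets in 7 of 24 (10 adjusted over the list alone; median 0.14, camera adjusted p = 2.1e-15), among them GCLM by 0.42 ± 0.07. Of 17 genes of fatty acid synthesis and LXR targets 4 rose (5 rose and 2 fell adjusted over the list alone; camera upward, adjusted p = 6.9e-08), with SCD at 0.41 ± 0.05 and FADS1 at 0.39 ± 0.04. The median of that list was 0.10 and its mean -0.14. CXCL1, a chemokine gene, fell by 0.77 ± 0.09. The test called 544 genes, 193 higher and 351 lower. The count was 263 without high replicate 1, 279 without low replicate 1, 336 without high replicate 2, 292 without low replicate 2 and 828 with the GC and length trend removed.

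Rehmanniae Radix Preparata at the high against the low dose raised AHR targets and mitotic genes by small amounts and lowered hepatocyte marker genes. CYP1A1 rose from 0.143 ± 0.0718 to 0.942 ± 0.160 CPM (SD, n = 3 per dose; log2 fold change 2.7 ± 0.44, edgeR adjusted p = 0.00029). ALDH3A1, an aldehyde dehydrogenase gene (ENSG00000108602, chromosome 17, 19737984 to 19748943), rose by 0.45 ± 0.05 and CYP1B1 by 0.36 ± 0.04. Of 10 AHR targets 4 rose, also adjusted over the list alone (median 0.18, camera adjusted p = 3.4e-17). Mitotic genes rose in 9 of 24 cases (21 adjusted over the list alone; median 0.20, camera adjusted p = 1.4e-34), among them BUB1 by 0.23 ± 0.04, and DNA replication genes in 3 of 24 (18 adjusted over the list alone; median 0.15, camera adjusted p = 4.2e-22). Of 8 hepatocyte genes 5 fell, also adjusted over the list alone (median -0.29, camera adjusted p = 2.8e-15), with APOB at -0.57 ± 0.10 and SERPINA1 at -0.52 ± 0.08. VIL1 fell by 1.16 ± 0.20 and CLDN2 by 0.76 ± 0.12. HMOX1 rose by 0.32 ± 0.06 from 43.8 ± 1.86 CPM, with 57.1 ± 2.83 CPM in vehicle. The test called 133 genes, 55 higher and 78 lower. The count was 64, 88 and 84 without high replicate 1, 2 or 3, and 80, 71 and 52 without low replicate 1, 2 or 3. It was 213 by DESeq2 and 252 with the GC and length trend removed.

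Angelicae Gigantis Radix at the high against the low dose raised HMOX1 and CYP1B1 and lowered genes of the list of fatty acid synthesis and LXR targets. HMOX1 rose by 0.59 ± 0.07 from 41.8 ± 1.60 to 63.0 ± 0.237 CPM (SD, n = 2 per dose; edgeR adjusted p = 3.8e-06) and CYP1B1 by 0.41 ± 0.05. HMOX1 stood at 57.1 ± 2.83 CPM in vehicle, and its low and medium doses lay below vehicle (log2 fold change -0.449 ± 0.069 and -0.303 ± 0.069). The receptor gene NOTCH3 (ENSG00000074181, chromosome 19, 15159038 to 15200981) rose by 0.56 ± 0.08. Of 17 genes of fatty acid synthesis and LXR targets 5 fell (7 adjusted over the list alone; median -0.18, camera adjusted p = 2.6e-18), among them SCD by 0.36 ± 0.05 and FADS1 by 0.22 ± 0.04. Of 8 hepatocyte genes 3 fell (4 adjusted over the list alone; median -0.28, camera adjusted p = 1.6e-10), with FGB at -0.29 ± 0.05 and FGA at -0.28 ± 0.04. HP fell by 1.15 ± 0.20. Of 24 DNA replication genes 1 rose over all genes and 12 adjusted over the list alone (median 0.15, camera adjusted p = 1.8e-18). AHR targets rose in 3 of 10 cases (4 adjusted over the list alone; median 0.14, camera adjusted p = 6.3e-08). Of these, CYP1A1 stood at 2.35 ± 0.52 (edgeR adjusted p = 0.016), and the edgeR adjusted p was 0.096 without high replicate 2, 0.14 without high replicate 3, 0.18 without low replicate 2 and 0.20 without low replicate 3. The test called 86 genes, 22 higher and 64 lower. The count was 56 without low replicate 2, 36 without high replicate 3, 33 without low replicate 3, 164 without the filter and 145 with the GC and length trend removed.

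Cinnamomi Cortex at the high against the low dose lowered hepatocyte marker genes and raised mitotic genes by small amounts. SERPINA1, the alpha-1 antitrypsin gene (ENSG00000197249, chromosome 14, 94376747 to 94390693), fell by 0.68 ± 0.08 from 41.1 ± 3.42 to 25.6 ± 0.921 CPM (SD, n = 3 per dose; edgeR adjusted p = 1.8e-07), and TF, the transferrin gene, by 0.43 ± 0.09. Of 8 hepatocyte genes 5 fell (6 adjusted over the list alone; median -0.30, camera adjusted p = 6.2e-14). GJB1, a gap junction gene, fell by 0.94 ± 0.16, RAB37 by 0.84 ± 0.14 and GSTA1 by 0.71 ± 0.11, the last uncertain because of its close copy GSTA2. PI3, an elastase inhibitor gene (ENSG00000124102, chromosome 20, 45174876 to 45176544), rose by 0.74 ± 0.09 and OLFML2A by 0.50 ± 0.09. Mitotic genes rose in 7 of 24 cases (16 adjusted over the list alone; median 0.16, camera adjusted p = 2.8e-20) and DNA replication genes in 2 of 24 (13 adjusted over the list alone; median 0.12, camera adjusted p = 1e-13). Of 17 genes of fatty acid synthesis and LXR targets 2 fell (9 adjusted over the list alone; median -0.11, camera adjusted p = 1.6e-08). CYP1B1 rose by 0.22 ± 0.04, while HMOX1 (-0.01 ± 0.06) and CYP1A1 (-0.03 ± 0.58) did not pass the test. The proliferation marker MKI67 also did not pass it (0.15, edgeR adjusted p = 0.63). MKI67 was at 282 ± 8.38 CPM at the low dose and 395 ± 63.9 CPM in vehicle. The test called 257 genes, 102 higher and 155 lower. The count was 163 without high replicate 1, 171 without high replicate 2, 167 without low replicate 2, 168 without low replicate 3 and 454 with the GC and length trend removed. It was 113 in a fit of only the libraries compared.

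Extracts that share a code series were compared directly at the high dose, which uses no vehicle library. Angelicae Gigantis Radix stood below Paeoniae Radix in 22 of 23 hypoxia genes, also adjusted over the list alone (median -1.59, camera adjusted p = 6.8e-84), in all 22 p53 targets (22 adjusted over the list alone; median -0.75, camera adjusted p = 1e-15) and in 21 of 24 cholesterol synthesis genes with 1 above, also adjusted over the list alone (median -0.60, camera adjusted p = 8e-15). It stood above it in 21 of 24 mitotic genes (21 adjusted over the list alone; median 0.40, camera adjusted p = 8.7e-11) and in 12 of 15 heat shock genes (13 adjusted over the list alone; median 0.59, camera adjusted p = 4.9e-07). IGFBP3 differed by -3.73, PCDH1 by -2.93, CLEC2B by -2.86 and DDIT3 by -1.73 on the log2 scale, and ANGPT4 by 3.12, SEC31B by 2.75 and MKI67 by 0.81. This comparison called 9157 genes, 4476 higher and 4681 lower in Angelicae Gigantis Radix.

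Cnidii Rhizoma stood below Rehmanniae Radix Preparata at the high dose in 10 of 15 glucocorticoid receptor targets and above it in 1 (13 and 1 adjusted over the list alone; median -0.30, camera adjusted p = 5.6e-21), and in 3 of 5 metallothionein genes (4 adjusted over the list alone; median -0.56, camera adjusted p = 1.9e-08). PLIN1 was higher in Cnidii Rhizoma by 1.28, ANGPTL4 by 1.18 and HMOX1 by 0.96. HP was lower, at -1.70, as were BEST2 at -1.3, STAC2 at -1.23 and CYP1A1 at -1.72. This comparison called 1319 genes, 614 higher and 705 lower in Cnidii Rhizoma.

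Astragali Radix stood below Cinnamomi Cortex at the high dose in all 24 mitotic genes (24 adjusted over the list alone; median -1.66, camera adjusted p = 6.6e-33) and in 21 of 24 DNA replication genes, with 1 above, also adjusted over the list alone (median -0.90, camera adjusted p = 2.2e-11). It stood above it in 20 of 23 hypoxia genes (21 adjusted over the list alone; median 1.13, camera adjusted p = 4.6e-27) and 22 of 24 cholesterol synthesis genes (22 adjusted over the list alone; median 0.82, camera adjusted p = 9.9e-20). Of 20 lysosome genes 18 were higher and 1 lower, also adjusted over the list alone (median 0.85, camera adjusted p = 9.4e-18). MNS1 differed by -5.13, CENPE by -4.67 and MKI67 by -2.93, and CYP1A1 by 3.23, ALDOC by 2.99 and HMOX1 by 1.89. The mitochondrial share and the GC measure differed between these libraries as given above, and log2 fold changes correlated with GC content (Spearman rho = 0.58 across 10728 genes). CDKN1A differed by 0.97, and by 0.47 with the GC and length trend removed. This comparison called 11637 genes, 5822 higher and 5815 lower in Astragali Radix.

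Against vehicle, many genes were called for every extract at every dose, and most differed by less than 2-fold. At the high dose 6691 genes were called for Angelicae Gigantis Radix, 10721 for Paeoniae Radix, 8571 for Cnidii Rhizoma, 7823 for Rehmanniae Radix Preparata, 11366 for Astragali Radix, 8759 for Cinnamomi Cortex and 8319 for Sagunja-tang. At the low dose the counts ran from 7507 for Angelicae Gigantis Radix to 9164 for Astragali Radix, and at the medium dose from 7229 to 9763 for the same extracts. The mean of the low-dose groups of these 7 extracts (18 libraries), each group with equal weight, was set against vehicle. This contrast, chosen after the data were seen, gave 9950 genes, 4832 higher and 5118 lower. BAAT, a bile acid conjugation gene, was higher by 1.10 on the log2 scale in that contrast and ZFPM1 lower at -1.16, while the pseudogene RPL7AP6 (1.28), SULT1A3 (-1.92, with a near-identical copy) and the unnamed locus AC008622.2 (-3.39) are uncertain. The log2 fold changes of that contrast correlated with GC content (Spearman rho = -0.79 across 10728 genes), and those of the high doses with rho between -0.791 and -0.749 apart from Paeoniae Radix (-0.389) and Astragali Radix (0.204). Vehicle libraries bear a code series shared with no extract, so extract and series are confounded here, although all titles name the same batch (BatchD). Without high replicate 2 the count for Angelicae Gigantis Radix was 4429. With the GC and length trend removed the high-dose counts were 3067 for Angelicae Gigantis Radix, 5531 for Cnidii Rhizoma, 4571 for Rehmanniae Radix Preparata, 5166 for Cinnamomi Cortex and 5287 for Sagunja-tang. They were 10574 for Paeoniae Radix and 11538 for Astragali Radix. After that removal the counts ran from 3569 for Angelicae Gigantis Radix to 6431 for Astragali Radix at the low dose, and from 3835 to 10058 for the same extracts at the medium dose.

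**Figure D4:**
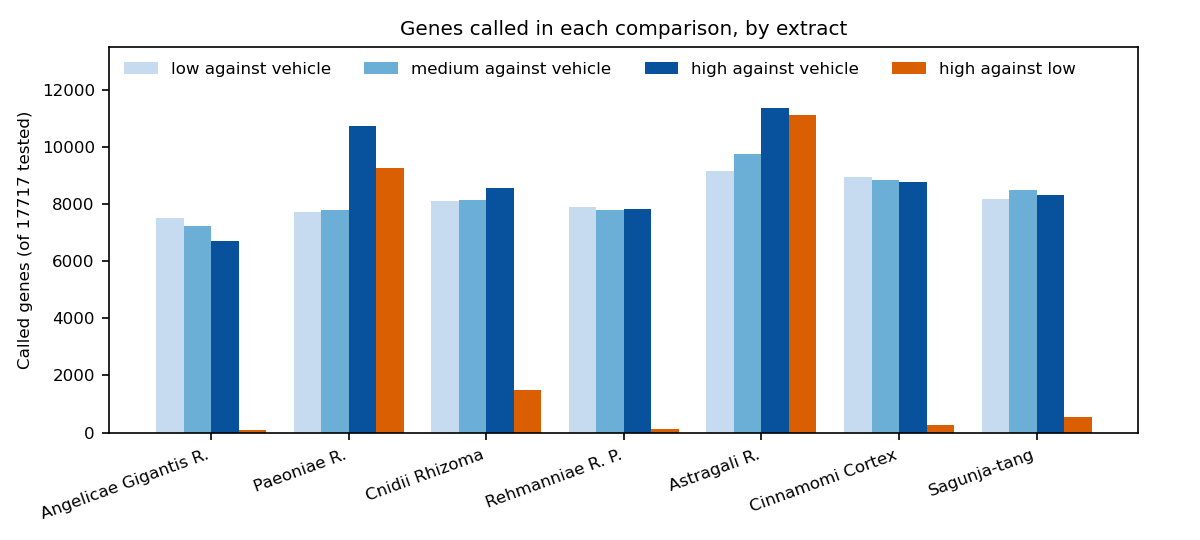
Bars give the number of called genes of 17717 tested (vertical axis, from 0) for each replicated extract (horizontal axis) at the low, medium and high dose against vehicle and at the high against the low dose. Against vehicle every bar lies between 6691 and 11366, whereas high against low dose runs from 86 for Angelicae Gigantis Radix to 11136 for Astragali Radix.

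Several of the gene groups that moved with dose also differed from vehicle at the high dose, and the counts for them adjusted over the list alone were the same unless given. Others did not pass the set test against vehicle, such as the hepatocyte list with Rehmanniae Radix Preparata (camera adjusted p = 0.93), Cinnamomi Cortex (0.998) and Angelicae Gigantis Radix (0.865). With Paeoniae Radix all 23 hypoxia genes were higher (median 1.84, camera adjusted p = 9.4e-81), with IGFBP3 at 4.04 ± 0.09 and HK2 at 3.14, and LEFTY1 was lower at -2.81. With Astragali Radix all 24 mitotic genes were lower (median -1.52, camera adjusted p = 4.1e-38), all 24 cholesterol synthesis genes (median 0.82, camera adjusted p = 1.1e-22) and all 20 lysosome genes (median 0.85, camera adjusted p = 7.8e-21) were higher, MKI67 was at -3.26 and HMOX1 at 1.45. At the medium dose of Astragali Radix MKI67 was already at -1.90, with 106 CPM against 395 ± 63.9 CPM in vehicle. With Cnidii Rhizoma 12 of 15 glucocorticoid receptor targets were lower and 1 higher (median -0.40, camera adjusted p = 0.0002), 4 of 5 metallothionein genes were lower and 1 higher (median -1.06, camera adjusted p = 0.0014), HP was at -1.80 and the circadian gene DBP at -1.51. With Sagunja-tang 8 of 10 AHR targets were higher (median 0.45, camera adjusted p = 1.2e-13), with CYP1A1 at 6.07 and CYP1B1 at 1.34, and NR4A1, an immediate early receptor gene, was lower at -1.65. CYP1A1 also stood above vehicle with Paeoniae Radix (3.07), Astragali Radix (3.01), Rehmanniae Radix Preparata (2.14) and Angelicae Gigantis Radix (2.05). Ribosomal protein genes were lower in 17 of 28 cases and higher in 1 with Rehmanniae Radix Preparata (18 lower adjusted over the list alone; median -0.22, camera adjusted p = 0.00012, adjusted p = 0.63 with an estimated correlation).

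Samul-tang combines the 4 roots Angelicae Gigantis Radix, Paeoniae Radix, Cnidii Rhizoma and Rehmanniae Radix Preparata, and its single libraries per dose allow no test and no replicate check. CYP1A1 was at 2.47 CPM at the high dose against 0.214 ± 0.0824 CPM in vehicle, a difference of 1.52 in log2(CPM + 1), CYP1B1 differed by 0.85, HMOX1 by 0.39 and NQO1 by 0.36. The differences of largest size were those of AC093484.3 (-3.66), AC002996.1 (-2.05), SULT1A3 (-2.02), AC124068.1 (2.38) and PAPPA-AS1 (2.10), all of them unnamed, antisense or copied loci and so uncertain. Of these, SULT1A3 (-2.11), AC124068.1 (2.18) and PAPPA-AS1 (1.96) were as far from vehicle at the low dose. SULT1A3 and AC124068.1 (2.48) also differed alike in the averaged low-dose contrast of the other extracts. The vehicle libraries themselves spread widely for PAPPA-AS1 (6.225 ± 6.063 CPM) and AC124068.1 (1.326 ± 2.297 CPM). Of 23 hypoxia genes 19 were higher (median 0.32, percentile 100 among matched random lists), as were AHR targets (median 0.34, percentile 99.71), whereas metallothionein genes were lower (median -0.75, percentile 0; -0.35 and 3.52 at the low dose, and -0.06 and 12.5 between the high and the low dose). Between the high and the low dose the difference was positive for all 24 mitotic genes (median 0.18), all 23 hypoxia genes (median 0.20), 9 of 10 AHR targets (median 0.27) and all 13 mitochondrially encoded genes (median 0.22). It was negative for 13 of 15 glucocorticoid receptor targets (median -0.10), 7 of 8 hepatocyte markers (median -0.20) and 14 of 17 genes of fatty acid synthesis and LXR targets (median -0.08). The share of counts on mitochondrial genes was 15.3% at the high and 14.0% at the low dose. At the high dose 101 genes differed from vehicle by at least 2-fold, 27 higher and 74 lower, and the count was 170 with a pseudocount of 0.5 CPM and 15 with 5 CPM.

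The dose responses of the extracts were set beside each other by the correlation, across 17717 genes, of the high minus low difference in log2(CPM + 1). No library is shared between extracts in this measure, and genes are not independent replicates. Of 28 pairs, Paeoniae Radix and Astragali Radix had the highest correlation (r = 0.453, and 0.431 to 0.458 without any 1 library) when all genes were used, followed by Rehmanniae Radix Preparata and Sagunja-tang (0.297), Angelicae Gigantis Radix and Cinnamomi Cortex (0.267) and Cnidii Rhizoma and Cinnamomi Cortex (0.253). Without any 1 library these 3 ran from 0.243 to 0.3, 0.185 to 0.267 and 0.215 to 0.264. For medium minus low dose the 4 pairs were at 0.253, 0.084, -0.007 and 0.045. The lowest were those of Astragali Radix with Rehmanniae Radix Preparata (-0.1, and -0.123 to -0.044 without any 1 library), Cinnamomi Cortex (-0.072, -0.108 to -0.009) and Cnidii Rhizoma (-0.058, -0.09 to -0.012). For genes with a mean of at least 10 CPM the order changed, with Rehmanniae Radix Preparata and Sagunja-tang at 0.54, Angelicae Gigantis Radix and Cinnamomi Cortex at 0.505 and Paeoniae Radix and Astragali Radix at 0.462. The SD of the difference across genes was 0.552 in Astragali Radix and 0.461 in Paeoniae Radix, against 0.107 to 0.176 in the other 6.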

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

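The tests of the GC trend behind the vehicle difference and of a separate preparation of vehicle were chosen only after the result was seen. Of the tests of the mitosis list, the GC correction and the omission of mitochondrial genes were added after its fall was seen and before their own results, and the other tests in this part were set before. Dose effects (high minus low) were compared between extracts of the same code series by an interaction contrast in the edgeR fit. They differed in 6956 genes between Angelicae Gigantis Radix and Paeoniae Radix, in 406 between Cnidii Rhizoma and Rehmanniae Radix Preparata and in 9712 between Astragali Radix and Cinnamomi Cortex. Genes called in opposite directions in both extracts of a pair numbered 25, 5 and 117. Of the panel genes, the dose effect of Angelicae Gigantis Radix minus that of Paeoniae Radix was -0.631 for CYP1B1, 0.575 for HMOX1, 0.241 for NQO1, -1.92 for DDIT3, 1.09 for HSPA1A, -1.19 for CDKN1A, 0.799 for MKI67 and -1.54 for CXCL8. For Cnidii Rhizoma minus Rehmanniae Radix Preparata it was -2.65 for CYP1A1, 0.938 for HMOX1 and 1.01 for CXCL8. For Astragali Radix minus Cinnamomi Cortex it was 2.61 for CYP1A1, 0.272 for CYP1B1, 1.72 for HMOX1, 0.477 for NQO1, 0.628 for DDIT3, 0.862 for CDKN1A and -2.85 for MKI67.

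Vehicle libraries stood apart from extract libraries even at the low dose, with 9950 genes called. Once the GC and length trend was removed, 6750 genes were still called. That count argues only against the trend as fitted by the splines as the whole cause. A GC or length effect that the splines do not capture was not tested. Low-dose groups of different extract series differed in a median of 0.5 genes (18 pairs), against 3 within a series (3 pairs). This argues only against a series difference in called genes of the kind seen among extracts. No extract bears the vehicle series, so a difference of that series alone was not tested. The log2 fold changes of these pairs correlated with GC content by rho of -0.431 to 0.586 between series and -0.176 to 0.129 within a series. An effect already complete at the low dose stays open. Of the genes called, 0.10, 0.18, 0.35 and 1.12% moved on in the same direction to the high dose of Angelicae Gigantis Radix, Rehmanniae Radix Preparata, Cinnamomi Cortex and Sagunja-tang, while 0.61, 0.9, 1.54 and 2.88% moved back. The onward shares lie under the bound of 5% set in advance to exclude such an effect. That bound was wrong by construction because a complete effect moves no further. In Cnidii Rhizoma, Astragali Radix and Paeoniae Radix 5.04, 18.09 and 29.47% moved on while 5.57, 56.78 and 31.78% moved back. A separate preparation of vehicle cannot be told apart from treatment, because vehicle has its own code series and the DMSO share of the extract libraries is not given in the sources used here. The titles name the same batch (BatchD) for vehicle and extracts. The 3 vehicle libraries, from 0.549 upward on the GC measure, lie above all low-dose libraries (up to 0.003).

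All 24 mitotic genes fell at the high dose of Astragali Radix, in libraries with a higher mitochondrial share and GC trend. The median was -1.26 with the GC and length trend removed (camera adjusted p = 3.3e-45), -1.605 without high-dose replicate 3, the library of fewest counts (camera adjusted p = 1.7e-28), and -1.59 with the 15 mitochondrial genes among those tested left out of the counts (camera adjusted p = 2.2e-33). The first value argues against the fitted trend, and the value without replicate 3 against that library, as the whole cause. The omission of the mitochondrial genes decides nothing on their share. TMM, a trimmed mean, already limits the weight of a few genes in the main fit, so that value could hardly move. A lower share of dividing cells is therefore a hypothesis that these tests leave standing, found and tested on the same libraries; cell number and viability were not analysed here.

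Other splits of the libraries into groups of the same sizes were tested where each group had 3. In the 18 comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, was the highest in each. The real and highest other counts, in a fit of those libraries, were for Cnidii Rhizoma 7976 and 1 (high against vehicle), 7571 and 0 (medium), 7529 and 1 (low) and 1282 and 0 (high against low). They were 7393 and 0, 6566 and 1, 7403 and 0, and 145 and 4 for Rehmanniae Radix Preparata, 10113 and 0, 8806 and 0, 8581 and 0, and 10375 and 0 for Astragali Radix, and 8011 and 0, 8258 and 0, 8356 and 0, and 113 and 5 for Cinnamomi Cortex. They were 1370 and 1 for Cnidii Rhizoma against Rehmanniae Radix Preparata and 10798 and 0 for Astragali Radix against Cinnamomi Cortex. For the low-dose libraries against vehicle, 1 of 100 splits, the real one, gave as many genes (9564, the highest other 3534). The low-dose libraries were pooled as 1 group in these fits. That share is the smallest that 100 splits can give, and the contrast was chosen after the data were seen. The splits thus show that few random divisions of these libraries give as many calls, and they cannot separate treatment from code series.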

How the results depend on the processing

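The removal of each library's GC and length trend and the contrast of all low-dose libraries with vehicle were chosen after the data were seen. Of the checks on the mitosis list, the GC correction and the omission of mitochondrial genes were added after its fall was seen and before their own results, and the other alternatives were set before. All 32 counts of called genes stayed within 1.5 times of their value with RLE scaling, and all 32 with the replicate number as a block, which ended no call among the 515 named genes, gave 6 of them a call and ended 3 of 201 list calls. In the 3 comparisons where every same-numbered correlation was above 0.1, the block changed no call of a named gene or list. Correlations of that size do not establish that the libraries were paired. The counts there went from 11366 to 11449 for Astragali Radix high against vehicle, from 8836 to 8922 for Cinnamomi Cortex medium against vehicle and from 133 to 177 for Rehmanniae Radix Preparata high against low. DESeq2 kept 31 of the 32 counts and 494 named genes, ended 5 calls and added 1, while the remaining named genes, CYP1A1 of Sagunja-tang high against low among them, got no adjusted p from it. RLE kept 513 named genes and 199 of 201 list calls, and ended 2. The absence of a filter kept 31 counts and 500 named genes. A fit of only the groups compared kept 7 of 7 counts at the high dose against vehicle. With an estimated correlation 63 of the 201 list calls were lost and 138 held; leaving out a library changed 34 of them, 93 of the 515 named genes and 5 of the 32 counts. The GC correction left 414 named genes with their direction and call, ended 37 calls, added 22 and reversed 42 signs. It ended 9 of the 201 list calls and kept 192. Groups of 2 leave a single library when another is left out, which is then assumed to vary like the other groups. At 1.3-fold, simulation recovered 50% of changed genes in Angelicae Gigantis Radix high against low, so small changes are missed at this depth and number of libraries.

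Counts of all called genes that moved by over 1.5 times were these, and the cause was not tested. With the GC and length trend removed, the high dose against vehicle gave 3067 genes for Angelicae Gigantis Radix, 5531 for Cnidii Rhizoma, 4571 for Rehmanniae Radix Preparata, 5166 for Cinnamomi Cortex and 5287 for Sagunja-tang. The medium dose gave 3835, 4373 (Paeoniae Radix), 4498, 4943, 5191 and 4944, and the low dose 3569, 3991, 4720, 4798, 5739 and 4297, in the same order of extracts. The high against the low dose gave 145 for Angelicae Gigantis Radix, 252 for Rehmanniae Radix Preparata, 454 for Cinnamomi Cortex and 828 for Sagunja-tang. Without the filter Angelicae Gigantis Radix high against low gave 164, and by DESeq2 Rehmanniae Radix Preparata high against low gave 213. A fit of only the libraries compared gave 113 for Cinnamomi Cortex high against low, against 257 in the main fit. Leaving out 1 library gave 4429 to 6505 for Angelicae Gigantis Radix high against vehicle, and for the high against the low dose 33 to 58 for Angelicae Gigantis Radix, 52 to 88 for Rehmanniae Radix Preparata, 163 to 222 for Cinnamomi Cortex and 263 to 336 for Sagunja-tang, with fewer libraries in the fit. Counts of called genes at least 2-fold apart moved more often: of 32, 22 were lower by over 1.5 times with DESeq2, 19 lower and 2 higher with the GC and length trend removed, and 7 higher without the filter, and with 1 library left out 7 values were lower and 4 higher. For the high against the low dose, those of Paeoniae Radix (1965) and Astragali Radix (2611) stayed within 1.5 times in every setting. Samul-tang differed at least 2-fold from vehicle in 170, 157 and 128 genes at the high, medium and low dose with a pseudocount of 0.5 CPM and in 15, 16 and 18 with 5 CPM, since a larger pseudocount shrinks the differences of low genes. The median correlation of dose responses was 0.243 with a pseudocount of 5 CPM, 0.276 for genes with a mean of at least 10 CPM and 0.015 for medium minus low dose.

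Log2 fold changes against vehicle that changed sign when the GC and length trend was removed came to the following values. CDKN1A at the high dose came to 0.019 with Angelicae Gigantis Radix, 0.072 with Cnidii Rhizoma, 0.046 with Rehmanniae Radix Preparata, 0.050 with Cinnamomi Cortex and 0.095 with Sagunja-tang. At the medium dose CDKN1A came to 0.066 with Angelicae Gigantis Radix, 0.122 with Paeoniae Radix, 0.039 with Cnidii Rhizoma, 0.055 with Rehmanniae Radix Preparata, 0.030 with Cinnamomi Cortex and 0.027 with Sagunja-tang. At the low dose CDKN1A came to 0.045 with Angelicae Gigantis Radix, 0.007 with Paeoniae Radix, 0.050 with Cnidii Rhizoma, 0.049 with Rehmanniae Radix Preparata, 0.11 with Astragali Radix and 0.033 with Cinnamomi Cortex, and to 0.038 over all low-dose libraries. HMGCS1 came to -0.073 at the high dose with Cinnamomi Cortex and, at the medium dose, to -0.104 with Paeoniae Radix, -0.056 with Rehmanniae Radix Preparata and -0.087 with Cinnamomi Cortex. At the low dose HMGCS1 came to -0.042 with Angelicae Gigantis Radix, -0.037 with Paeoniae Radix, -0.041 with Cnidii Rhizoma, -0.068 with Rehmanniae Radix Preparata, -0.059 with Cinnamomi Cortex and -0.049 with Sagunja-tang, and to -0.042 over all low-dose libraries. HSPA1A came to 0.105 and 0.013 at the high dose with Cnidii Rhizoma and Rehmanniae Radix Preparata, to 0.044, 0.056 and 0.095 at the medium dose with Cnidii Rhizoma, Cinnamomi Cortex and Sagunja-tang, to 0.155, 0.084 and 0.034 at the low dose with Astragali Radix, Cinnamomi Cortex and Sagunja-tang, and to 0.003 over all low-dose libraries. CYP1B1 came to -0.038 at the medium dose of Cnidii Rhizoma and to -0.031 at the low dose of both Paeoniae Radix and Rehmanniae Radix Preparata, and HMOX1 to 0.015 at the low dose of Astragali Radix. The cause was not tested beyond the correction itself.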

Other observations

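The test of PPAR targets below was chosen only after the result was seen, while the tests of TFRC and of the sum of roots were set before. At the high against the low dose of Paeoniae Radix further groups moved that have not been described. Drug metabolism and transport genes fell in 10 of 12 cases (10 adjusted over the list alone; median -0.83, camera adjusted p = 1.4e-05), among them CYP2B6 by 2.69 ± 0.45 and GSTA1 by 1.68 ± 0.16, both uncertain because of close copies, and CYP3A7 was at 0 in both high-dose libraries, at least 2.44-fold lower. Lysosome and autophagy genes rose in 15 of 20 cases and fell in 1 (the same adjusted over the list alone; median 0.47, camera adjusted p = 4.5e-07). Mesenchymal and TGF-beta genes rose in 12 of 21 cases and fell in 3 (the same over the list alone; median 0.38, camera adjusted p = 1.1e-06), and fatty acid synthesis genes and LXR targets rose in 12 of 17 cases and fell in 3 (the same over the list alone; median 0.51, camera adjusted p = 0.00018). With Astragali Radix 20 of 24 nuclear genes of oxidative phosphorylation rose and 2 fell (21 and 2 adjusted over the list alone; median 0.47, camera adjusted p = 8.6e-05, adjusted p = 0.26 with an estimated correlation), beside the mitochondrial share given in the report. TRIB3, an ATF4 target, rose by 1.78 ± 0.05 with Astragali Radix.

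At the low dose, extracts other than Astragali Radix differed little from each other, with at most 11 genes called by edgeR per pair, whereas Astragali Radix at the low dose differed from each other extract in 495 to 1630 genes, 742 of them against Cinnamomi Cortex of the same code series.

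A hypothesis on the hypoxia genes of Paeoniae Radix was iron limitation, which stabilises HIF1 and would raise TFRC, the transferrin receptor gene, by at least 0.5. TFRC rose by 0.33 (0.328 ± 0.063, edgeR adjusted p = 2.3e-05), which is in the direction foreseen and below that bound, so the test left the hypothesis open. The ferritin gene FTH1 rose by 0.47, FTL was at 0.06, IREB2 at -0.29, the iron exporter gene SLC40A1 at -0.57 and EPAS1 at 0.49.

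PLIN1 and ANGPTL4, higher in Cnidii Rhizoma, are textbook targets of PPAR transcription factors, and a list of 14 PPAR targets, written after these results had been seen, was tested in Cnidii Rhizoma at the high against the low dose. Of its 12 tested members 7 rose and 1 fell (median 0.22, camera p = 4.49e-10, and 7.5e-06 with an estimated correlation), among them PLIN2 by 0.61 and CPT1A by 0.46, while CIDEC fell by 0.29. The list is not wholly independent of the results that prompted it. The value of 4.49e-10 is consistent with activation of PPAR targets as a set, a hypothesis found and tested on the same libraries.

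Samul-tang might act as the sum of its 4 roots. Its difference between high and low dose correlated across genes with the mean difference of the 4 roots at r = 0.265, above each root alone (0.118 for Angelicae Gigantis Radix, 0.189 for Paeoniae Radix, 0.188 for Cnidii Rhizoma and 0.155 for Rehmanniae Radix Preparata), and at 0.224 without Paeoniae Radix. A mean of several noisy differences can correlate better than each of them for that reason alone, and each dose of Samul-tang is a single library, so this may reflect lower noise rather than a sum.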
